A study of Mus musculus with 12 samples.

How the data were processed

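The authors deposited 1 table of expected counts and 1 table of TPM per gene, made by salmon; its version and the annotation used are not given in the sources used here, and the genome named is mm10. Libraries were made from polyadenylated RNA extracted with trizol and chloroform, using a Tecan Universal Plus mRNA-Seq kit. The raw reads were not used here. The deposited expected counts were rounded to whole numbers, and the deposited TPM values were used for an alternative only. The column names carry the letters B and P, which the sources do not explain, and the diet of each column rests on the column number in the submitters' descriptions. The table holds 24279 genes and no transcripts of the mitochondrial genome.

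Depth ran from 39339190 to 48475963 counts per library. At this depth counting error is small beside the spread between libraries, for which the common biological coefficient of variation was 0.332. The 100 most abundant genes took 18.9 to 24.1% of counts. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15186 genes and removed 9093. Scaling was by TMM, with factors from 0.91 to 1.08. CPM are counts per 1000000 scaled in this way, and log2 CPM used a prior count of 2.

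All 12 libraries entered 1 model with a mean per group, fitted by edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. The contrasts were mutant against wild type at each folic acid level, fortified against moderate folic acid in each genotype, their averages and the interaction. Adjusted p values follow Benjamini and Hochberg over all tested genes of a contrast, with a threshold of 0.05. SDs are between the 3 libraries of a group, and SEs are those of the fitted log2 fold change. Groups were said not to overlap for a gene when every library of one lay above every library of the other.

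Gene lists were fixed before the data were examined, as were the contrasts, the thresholds, the rule for named genes and the alternatives, except those listed as later choices. Of 37 lists 36 had at least 3 tested genes; the list of mitochondrial transcripts had 0 in the table. Lists were tested by camera of limma 3.58.1 with its preset correlation between genes of 0.01, adjusted over the 36 lists. Camera with an estimated correlation and fry were run as alternatives. Each list's genes were also adjusted over the list alone. A library's score for a list is the mean over its genes of log2 CPM minus that gene's mean over the 12 libraries.

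Named genes were, for each of the 4 comparisons, the 10 with the largest positive and the 10 with the largest negative log2 fold change among those passing. They needed a mean of at least 5 CPM in the higher group and groups that did not overlap, and could not be model or clone names, sex-linked or members of multi-copy families. Where fewer than 5 passed in a direction, the places were filled to 5 by smallest p. For the averages and the interaction 10 genes in all were named. Added to these were 14 genes of the mutation, Hedgehog signalling, folate metabolism and DNA methylation, and up to 4 genes with the smallest p of each list.

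The alternatives were DESeq2 1.42.0, limma-voom with quality weights, limma on log2(TPM + 1) and log2(TPM + 0.1), median-of-ratios scaling, library totals alone, no low-count filter, and a filter of 1 CPM in 3 libraries. Further ones were a block by replicate number, fits on only the groups compared, a test against a 1.5-fold change with glmTreat, a sex-linked score as covariate, and leaving out each library in turn. DESeq2 gave no adjusted p for 1492, 23, 318 and 1785 genes in the 4 comparisons. Later choices, made after the data were seen, were the removal of each library's trend on transcript length, on GC content or on both, leaving out 3 libraries, and keeping only the 8 libraries with Xist. Length and GC trends were natural splines with 5 degrees of freedom, removed through offsets, for the 14616 genes with a length. A library was taken to carry Xist with at least 1000 counts, and to lack Y-linked transcripts with fewer than 10 counts over 4 genes.

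The procedure was tested on simulated data with 200 changed genes in each of 5 runs. At 2-fold it recovered 19.2, 21.6, 19.2 and 22.4% of changed genes in the 4 comparisons, and 53.2 and 46.8% for the averages of genotype and folic acid. At 4-fold it recovered 62.8, 67.6, 67.2 and 66% in the 4 comparisons. In separate runs, each of 36 lists was raised 1.5-fold in mutant cells at moderate folic acid, and 31 were recovered. A mean of 0.111 other lists was called, while wrong splits of the real moderate libraries called up to 18. The simulated genes were drawn independently, so these runs do not test the preset correlation between genes.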

Results

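Polyadenylated RNA was sequenced from primary mouse embryonic fibroblasts, cells grown out of embryos at embryonic day 12.5. The embryos were wild type or homozygous for a change in Rsg1 (Rsg1L3P/L3P), and came from the F3 generation of mice kept on a moderate (2 ppm) or a fortified (10 ppm) folic acid diet. The culture medium held 225 ng/mL folic acid for the moderate cells and 3600 ng/mL for the fortified cells. Diet and medium changed together, so their effects cannot be told apart, and folic acid level here means both. Rsg1 encodes a small GTPase-like protein of the CPLANE complex, which is needed to build primary cilia. Each of the 4 groups had 3 libraries, so that n = 3 throughout for group means. The labels do not say whether the 3 libraries of a group came from separate embryos or litters. The p values below therefore rest on the spread between libraries, which need not be that between embryos. The 12 libraries held 39339190 to 48475963 estimated counts, and 15186 of 24279 genes were tested. Rsg1 itself (ENSMUSG00000073733.4, chromosome 4, 141213956 to 141226756, plus strand of mm10) was near the lower end of detection. Its mean was 0.71 CPM ± 0.24 (SD) in moderate wild type, 0.93 ± 0.17 in moderate mutant, 0.88 ± 0.15 in fortified wild type and 0.76 ± 0.10 in fortified mutant cells.

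The libraries did not separate by group alone, but the second principal component (25.5% of variance) split them by folic acid. On it all moderate libraries lay between 9.87 and 39.7, and all fortified ones between -62.9 and 6.55. On the first principal component (30.2% of variance) moderate wild type 1, fortified mutant 2 and fortified mutant 3 lay at 68.0, 48.2 and 57.5, and the other 9 libraries between -68.6 and 4.74. The same 3 libraries had the highest mean scores of the skeletal muscle markers (1.15, 1.09 and 0.831 on the log2 scale relative to the mean of all libraries). They also had the highest scores of the neuron markers (1.52, 1.32 and 0.805). Correlations of log2 CPM within groups ran from 0.922 to 0.969 in moderate wild type cells and from 0.979 to 0.990 in moderate mutant cells. They ran from 0.956 to 0.986 in fortified mutant and from 0.967 to 0.980 in fortified wild type cells. Pairs from different groups reached 0.989, for fortified mutant 1 with fortified wild type 3, and moderate wild type 1 with fortified mutant 3 had 0.982. All 6 mutant libraries carried Xist and no Y-linked transcripts. Of the 6 wild type libraries, 2 carried Xist, 3 carried Y-linked transcripts and fortified wild type 2 carried neither (Fisher's exact test of Xist by genotype, two-sided p = 0.0606).

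**Figure D1:**
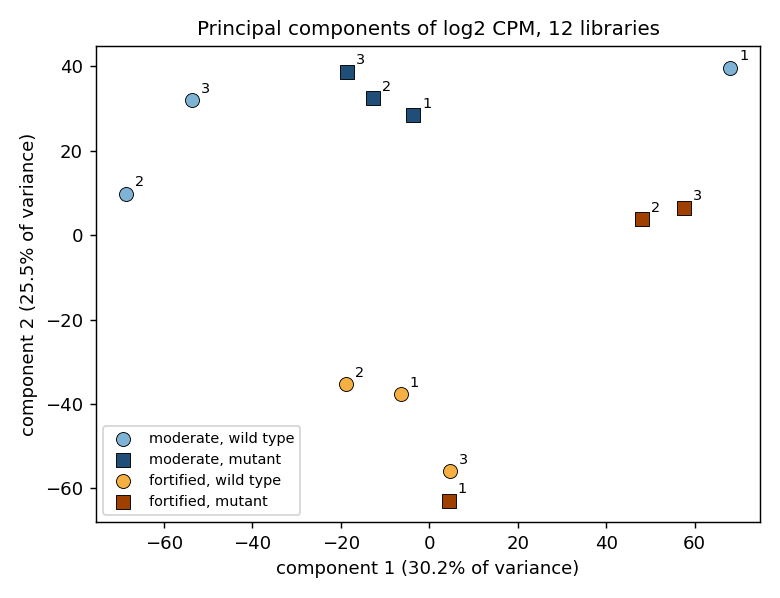
Scores of the 12 libraries on the first (x axis, 30.2% of variance) and second (y axis, 25.5%) principal components of log2 CPM. Points are libraries, coloured by group and numbered by replicate. On the first component 3 libraries of 2 groups lie at 48.2 or more, and all others at 4.74 or less. On the second, all moderate libraries lie at 9.87 or more and all fortified ones at 6.55 or less.

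The first comparison asked how mutant cells differed from wild type cells at moderate folic acid. Interferon response genes, cholesterol synthesis genes and genes of DNA replication had lower values in mutant cells, and genes of the fibroblast extracellular matrix had higher ones. The interferon list had a median log2 fold change of -1.09, with 27 of 28 genes negative. DNA replication genes were negative in 31 of 31 cases (median -0.60) and cholesterol synthesis genes in 22 of 22 (median -0.83). Matrix genes were positive in 30 of 35 cases (median 0.45). No single gene passed the threshold by edgeR, while DESeq2 called 50. With an estimated correlation between genes 0 of 36 lists passed camera (lowest adjusted p = 0.396), as by fry.

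By edgeR, 0 of 15186 genes passed an adjusted p of 0.05, and 1195 had an unadjusted p under 0.05. DESeq2 called 50 genes (23 higher and 27 lower in mutant cells), limma-voom 0 and limma on log2(TPM + 1) 0. The groups did not overlap for 1977 genes (13%), where chance gives 10%. Cmklr1, the receptor for chemerin, had the lowest adjusted p (0.198). It measured 16.0 ± 2.18 CPM in mutant and 6.93 ± 0.95 in wild type cells, a log2 fold change of 1.21 (SE 0.17), with all 3 mutant libraries higher. The other genes taken by smallest p all had an adjusted p of 0.588. Those with positive values were the methylcytosine dioxygenase Tet3 (0.85), Creb3l2 (0.66), the histone demethylase Kdm6b (0.75) and elastin (Eln, 1.55). Those with negative values were the replication factor Gins2 (-1.08), the actin nucleator subunit Arpc3 (-0.81), Dbi (-0.79), the peroxiredoxin Prdx1 (-0.96) and Raet1b (-1.21). Log2 fold changes were 0.57 for Dnmt3a and -0.07 for the Hedgehog receptor Ptch1, neither passing.

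Camera with a preset correlation called 19 of 36 lists at moderate folic acid, 12 higher and 7 lower in mutant cells. With an estimated correlation it called 0 (lowest adjusted p = 0.396), and fry called 0. Without moderate wild type 3 it called 11. The interferon list had the smallest preset adjusted p (6.62e-12; adjusted p = 0.396 with an estimated correlation). Its members included Oas1a (-2.60), Ifit1 (-2.09), Usp18 (-2.90) and Xaf1 (-1.46), and 4 of them were lower when adjusted over the list alone against 0 over all genes. DNA replication had an adjusted p of 4.97e-11 and cholesterol synthesis one of 5.1e-09. Both had an adjusted p of 0.571 with an estimated correlation. Among the cholesterol genes, Idi1 (-1.84), Fdps (-1.04), Fdft1 (-0.90) and Msmo1 (-1.33) were among 9 lower when adjusted over the list alone, against 0 over all genes; of the replication genes it was 1, Gins2. The matrix list had an adjusted p of 8.14e-09 (adjusted p = 0.466 with an estimated correlation), with Emilin1 at 1.09, Col3a1 at 0.82 and Fbn2 at 0.98. Eln alone was higher when adjusted over the list alone, against 0 over all genes. Hedgehog pathway genes were positive in 19 of 25 cases (median 0.26, adjusted p = 1.18e-05; adjusted p = 0.571 with an estimated correlation), with Gli2 at 0.58, Foxc2 at 0.85 and Prdm16 at 0.94. Adjusted over the list alone, 0 Hedgehog genes passed. These 5 lists were called without each of the 12 libraries in turn, but their medians moved. Without moderate wild type 1 the median was -0.28 for DNA replication, -0.46 for cholesterol synthesis, 0.29 for matrix and 0.63 for Hedgehog genes. It was 0.71 for matrix genes without moderate wild type 2 and 0.14 for Hedgehog genes without moderate wild type 3. The score of cholesterol synthesis was -1.09 in moderate wild type 3, below the moderate mutant libraries (-0.807, -0.938 and -0.902). Among the 8 libraries with Xist alone, a setting chosen after the data were seen that leaves 1 wild type library per diet, the Hedgehog median was -0.0122 (adjusted p = 0.986).

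Further lists called at moderate folic acid rested on single libraries, and none of them passed with an estimated correlation. Mitosis genes were negative in 28 of 28 cases (median -0.74, adjusted p = 2.74e-08), but without moderate wild type 1 their median was -0.25 (adjusted p = 0.0819). Their score was -1 in moderate wild type 3, below the moderate mutant libraries (-0.75, -0.864 and -0.474). Ribosomal protein genes were negative in 45 of 46 cases (median -0.43, adjusted p = 1.12e-07), and without moderate wild type 3 their median was 0.03 (adjusted p = 0.904). Without that library the calls also ended for planar cell polarity (median 0.27, adjusted p = 0.000129, then 0.0856), myofibroblast (0.33, 0.00105, then 0.0607) and TGF-beta and YAP genes (0.18, 0.00346, then 0.0785). The same held for canonical Wnt genes (0.17, 0.00346, then 0.667) and immediate early genes (0.23, 0.00467, then 0.168). Wnt genes also lost their call without moderate mutant 1 (adjusted p = 0.05), and immediate early genes without moderate mutant 3 (0.160).

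The medians of these lists moved as well. That of Wnt genes was -0.0401 without moderate wild type 3, 0.54 and 0.25 without moderate wild type 1 and 2, and 0.0858 and 0.27 without moderate mutant 1 and 3. That of planar cell polarity genes was 0.0998 and 0.41 without moderate wild type 3 and 1, and 0.16 without moderate mutant 1. Myofibroblast genes had 0.0749 without moderate wild type 3, and 0.145 and 0.51 without moderate mutant 1 and 3. TGF-beta and YAP genes had 0.114 without moderate wild type 3 and 0.116 without moderate mutant 3. Immediate early genes had 0.0642 and 0.0484 without the same libraries, and methylation enzymes 0.209 without moderate wild type 1. Cartilage markers had a median of 0.73 (adjusted p = 0.000232), which gave an adjusted p of 0.164 without moderate wild type 2 and 0.0534 without moderate wild type 3; the median was 2.18 without moderate wild type 1 and 0.0598 without moderate mutant 3. DNA and histone methylation enzymes had a median of 0.13 (adjusted p = 0.00515), and an adjusted p of 0.217 without moderate wild type 2. With an estimated correlation, each of these lists had an adjusted p of 0.571. Adjusted over the list alone, Col11a1 (0.94) of the cartilage markers, Itga11 (1.85) of the TGF-beta and YAP genes and Tet3 and Kdm6b of the methylation enzymes passed, against 0 over all genes.

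The other 5 lists called in mutant cells at moderate folic acid lay nearer the threshold. Hox genes of the trunk and tail had a median of -0.35 (adjusted p = 0.0295), which was 0.0689 without moderate wild type 1 (adjusted p = 0.925) and gave an adjusted p of 0.484 without moderate mutant 3. Genes of the ATF4 and unfolded protein response had a median of 0.32 (adjusted p = 0.0328), and an adjusted p of 0.838 without moderate wild type 1, 0.138 without moderate mutant 3 and 0.0535 without fortified wild type 2. Their median was 0.00736 and 0.0757 without moderate wild type 1 and moderate mutant 3, and 0.73 without moderate wild type 3 (0.00542). Inflammatory genes had a median of -0.40 (adjusted p = 0.0413), with an adjusted p of 0.169 and 0.0863 without moderate mutant 1 and 2, and 0.198 and 0.371 without moderate wild type 1 and 2. It was 0.0515 without fortified mutant 3 and 0.0561 without fortified wild type 1. Muscle markers had a median of 0.14 (adjusted p = 0.0413), which was -0.14 without moderate wild type 2 (adjusted p = 0.814) and -0.13 without moderate wild type 3 (0.491), but 0.87 without moderate wild type 1 (0.000101), and 0.0578 and 0.21 without moderate mutant 1 and 3. Their adjusted p was 0.0938 and 0.0529 without moderate mutant 1 and 2, 0.0611 without fortified mutant 3 and 0.0589 without fortified wild type 1. Markers of neural progenitors and glia had a median of 0.40 (adjusted p = 0.0459). This gave 0.272 without moderate mutant 2, 0.814 and 0.0534 without moderate wild type 2 and 3, and 0.0529 and 0.0611 without fortified mutant 2 and 3. Their median was 0.15 without moderate mutant 2, 0.151 without moderate wild type 2 and 0.78 without moderate wild type 1. With an estimated correlation the adjusted p was 0.709 for muscle markers and 0.571 for the other 4 lists, and 0 genes of these lists passed by either adjustment.

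The ciliary genes were the group closest to the function of Rsg1. The 59 genes of CPLANE and ciliogenesis had a median log2 fold change of -0.0887 between mutant and wild type cells at moderate folic acid (adjusted p = 0.487), and 0 passed either over all genes or adjusted over the list alone. At fortified folic acid the median was -0.0774 (adjusted p = 0.144), again with 0 by either adjustment. Ift172 had a log2 fold change of 0.45 and Wdr35 one of -0.27 at moderate folic acid. The 38 tested genes of folate and one-carbon metabolism had medians of -0.0898 (adjusted p = 0.536) and -0.00422 (adjusted p = 0.977) at moderate and fortified folic acid; at fortified folic acid the direction of the test was positive although the median was negative. The neural tube closure genes had medians of 0.0657 (adjusted p = 0.0774) and 0.0962 (adjusted p = 0.104).

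The second comparison set mutant against wild type cells at fortified folic acid. Matrix genes had lower values in mutant cells here, with 33 of 35 negative and a median log2 fold change of -0.59. Their scores were 0.408, -0.253 and 0.0121 in fortified mutant 1, 2 and 3, against 0.911, 0.601 and 0.627 in fortified wild type cells. Markers of skeletal muscle were positive in 24 of 24 cases (median 1.19) and markers of neurons in 19 of 20 (median 1.18). Fortified mutant 2 and 3 carried these values, and without the 3 libraries apart on the first component the medians were -0.31 and -0.25. Interferon genes were negative in 26 of 28 cases (median -0.42). No single gene passed by edgeR, while DESeq2 called 6. With an estimated correlation 0 of 36 lists passed camera (lowest adjusted p = 0.278).

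By edgeR 0 genes passed and 500 had an unadjusted p under 0.05, the lowest adjusted p being 0.939. A share of 0.05 would be expected without any difference, and 500 of 15186 genes lies below it. DESeq2 called 6 genes, all lower in mutant cells, limma-voom called 0 and limma on log2(TPM + 1) called 0. The groups did not overlap for 1561 genes (10.3%), where chance gives 10%. The genes with the smallest p, none passing, had positive values for Pbdc1 (0.68), Sept3 (1.19), Snhg3 (0.71), the Wnt effector Lef1 (1.02) and Bex1 (0.85). Negative values belonged to Figf (-1.95), the cartilage collagen Col10a1 (-2.79), Dmrt2 (-2.09), Ggta1 (-0.95) and Lrrc15 (-1.49). Col10a1 measured 8.00 ± 0.0707 CPM in mutant and 55.2 ± 61.1 in wild type cells, a spread that exceeded the wild type mean.

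Camera called 8 of 36 lists at fortified folic acid, 3 higher and 5 lower in mutant cells, against 0 with an estimated correlation and 0 by fry; without fortified mutant 2 it called 14. The matrix list had an adjusted p of 8.34e-14 (adjusted p = 0.278 with an estimated correlation), with Col5a1 at -0.95, Col6a3 at -1.22, Fbln2 at -1.69 and Postn at -0.99; 0 passed adjusted over the list alone. Muscle markers, among them Myog (1.51) and Tnnc2 (1.33), had an adjusted p of 8.55e-10. Neuron markers, among them Stmn2 (1.31) and Mapt (1.68), had one of 2.78e-06. For both lists the adjusted p was 0.716 with an estimated correlation, and 0 genes passed adjusted over the list alone. The muscle score was 1.09 in fortified mutant 2, 0.831 in fortified mutant 3 and -0.88 in fortified mutant 1. Without fortified mutant 2 the medians were 0.66 for muscle and 0.72 for neuron markers, and without fortified wild type 3 that of muscle markers was 1.9. Without the 3 libraries that stood apart on the first component, an alternative chosen after the data were seen, the medians turned to -0.31 for muscle (adjusted p = 0.692) and -0.25 for neuron markers (adjusted p = 0.178). That setting leaves 1 fortified mutant library, whose spread was taken from the other groups. Interferon genes (adjusted p = 4.01e-05; adjusted p = 0.716 with an estimated correlation) then had a median of 0.0542 (adjusted p = 0.864); it was -0.75 without fortified mutant 1 and -0.24 without fortified mutant 3. Bone markers (median -0.46, adjusted p = 0.0022; adjusted p = 0.716 with an estimated correlation) turned to 0.0857 (adjusted p = 0.864) in that setting, and gave an adjusted p of 0.123 without fortified wild type 2. Their median was -0.97 and -0.24 without fortified mutant 1 and 2, and -0.75 and -0.70 without fortified wild type 1 and 3. Ibsp (-3.83) and Col10a1 were lower when adjusted over the bone list alone, against 0 over all genes. Hypoxia and glycolysis genes had a median of -0.27 (adjusted p = 0.00163; adjusted p = 0.716 with an estimated correlation), which was -0.17 without fortified wild type 2. Ribosomal protein genes had a median of 0.21 (adjusted p = 0.000181) and macrophage and blood markers one of -1.13 (adjusted p = 0.00497). Both had an adjusted p of 0.93 with an estimated correlation. The ribosomal call ended without fortified mutant 1 (adjusted p = 0.113) or fortified wild type 1 (adjusted p = 0.193), and the blood marker call without the same libraries (0.145 and 0.0758). The ribosomal median was 0.12 without fortified mutant 1, 0.31 without fortified mutant 3 and 0.0829 without fortified wild type 1, and the blood marker median -0.68 without fortified wild type 1.

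How alike the genotype effects at the 2 folic acid levels were depended on the setting. Across 15186 genes, which are not independent replicates, their log2 fold changes had a Pearson r of 0.154 and a Spearman rho of -0.0854. The sign was the same for 43.5% of genes. The Pearson r was 0.411 by DESeq2. Without moderate wild type 2 the Pearson r was -0.137, and without moderate wild type 1 it was 0.459. It was 0.0458 without moderate wild type 3, 0.0271 without fortified mutant 1, and 0.0277 and 0.0615 without fortified wild type 2 and 3. Averaged over folic acid level, edgeR called 0 genes for genotype, with 705 at an unadjusted p under 0.05 and a lowest adjusted p of 0.986. The 705 genes too are below a share of 0.05 of the 15186. DESeq2 called 18 (5 higher, 13 lower) and limma-voom 0. The smallest p values belonged to Cmklr1 (0.57), Foxc2 (0.67), Slc12a2 (0.56), Prdm16 (0.88) and Zfp46 (0.43) among positive log2 fold changes. Fuca1 (-0.61), Raet1b (-0.90), Ggta1 (-0.81), the calcium-binding protein S100a4 (-2.76) and the stem cell antigen Ly6a (-1.99) had the smallest among negative ones, none passing. Of the averaged lists camera called 21, and with an estimated correlation 0. Interferon genes led these with a median of -0.88 (adjusted p = 1.73e-16; adjusted p = 0.17 with an estimated correlation).

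The third comparison asked how fortified differed from moderate folic acid in mutant cells. Over all genes, 12 of 22 genes of cholesterol synthesis, 6 of 28 of mitosis, 5 of 31 of DNA replication and 9 of 46 of ribosomal proteins rose. Of 25 stress genes of the ATF4 pathway 6 fell and 1 rose, with list scores of -0.0571, -0.46 and -0.753 in fortified mutant 1, 2 and 3. These 5 lists passed camera with its preset correlation, but had an adjusted p of 0.98 with an estimated correlation. Idi1, an isomerase of the cholesterol pathway, rose 6.64-fold, from 24.0 ± 2.86 to 159.7 ± 50.6 CPM (adjusted p = 0.0216). The mitotic securin Pttg1 rose 4.38-fold (5.55 ± 0.272 to 24.3 ± 3.96 CPM, adjusted p = 0.00977). Ppp1r15a, a stress-induced phosphatase subunit, was 4.87-fold lower (306.1 ± 123 to 62.9 ± 5.25 CPM, adjusted p = 0.0216). In each case all 3 fortified libraries lay on one side of all 3 moderate libraries.

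By edgeR 1053 of 15186 genes passed, 637 higher and 416 lower with fortified folic acid, of which 464 differed more than 2-fold. The groups did not overlap for any of the 1053, and for 5797 of all genes (38.2%), where chance gives 10%. DESeq2 called 2414 genes, of which 1037 were among the 1053 in the same direction. The count fell when single mutant libraries of either diet were left out: it was 0 without moderate mutant 1, 0 without moderate mutant 2 and 30 without moderate mutant 3. It was 204, 39 and 477 without fortified mutant 1, 2 and 3, and 593, 568 and 597 without fortified wild type 1, 2 and 3. Without moderate wild type 1 it was 2073 and without moderate wild type 3 it was 1638, while tested against a 1.5-fold change 0 genes passed. Wild type libraries are not part of this contrast and enter it through the filter, the scaling and the spread shared by all groups. On log2(TPM + 1), where the median of all genes lay at -0.23, limma called 2814 genes and 10.87% of them were higher, against 60.49% in the edgeR fit. With library totals as the only scaling 45.86% of 1184 were higher. All 1053 genes kept their sign on both scales.

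Among the genes named by rule, the largest rises after Idi1 were those of the kinase-associated phosphatase Cdkn3 (5.52-fold, SE 0.44 on the log2 scale, adjusted p = 0.0158) and the protease inhibitor Serpina3g (5.40-fold, adjusted p = 0.0229). The LIM protein Crip1 rose 5.25-fold (adjusted p = 0.00977) and the kinetochore subunit Spc24 4.98-fold (adjusted p = 0.0264). Acss2, which makes cytosolic acetyl-CoA, rose 4.69-fold, the centromere protein Cenpp 4.47-fold and the centromeric histone Cenpa 4.33-fold. Thbs4, a matrix thrombospondin, rose 4.46-fold (adjusted p = 0.0486), with 92.3 ± 81.7 CPM in fortified cells. Without fortified mutant 1 its log2 fold change went from 2.16 to 1.13 (adjusted p = 0.163).

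Ppp1r16b, a regulatory subunit of protein phosphatase 1, was 21-fold lower (19.9 ± 10.9 to 0.944 ± 0.328 CPM, adjusted p = 0.0138). Trim66 was 14.0-fold lower and Gch1, the first enzyme of tetrahydrobiopterin synthesis, 12.6-fold lower. The BMP antagonist Grem1 fell 9.47-fold (123.1 ± 89.7 to 13 ± 4.57 CPM, adjusted p = 0.0359). P2rx3, an ATP-gated channel of sensory neurons, was 9.19-fold lower, Sh3tc2 9.13-fold, Klf15 8.13-fold, Gpnmb 7.24-fold and Avil 6.60-fold lower. Without moderate mutant 3 the log2 fold change of Gch1 went from -3.66 to -3.05 and that of Grem1 from -3.24 to -2.46. Without fortified mutant 1 that of Trim66 went from -3.81 to -4.91 and that of P2rx3 from -3.20 to -4.26. Without moderate mutant 1, 2 or 3, 0 of the 20 genes taken by the rule passed, the lowest adjusted p being 0.0539, 0.0749 and 0.0516.

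**Figure D2:**
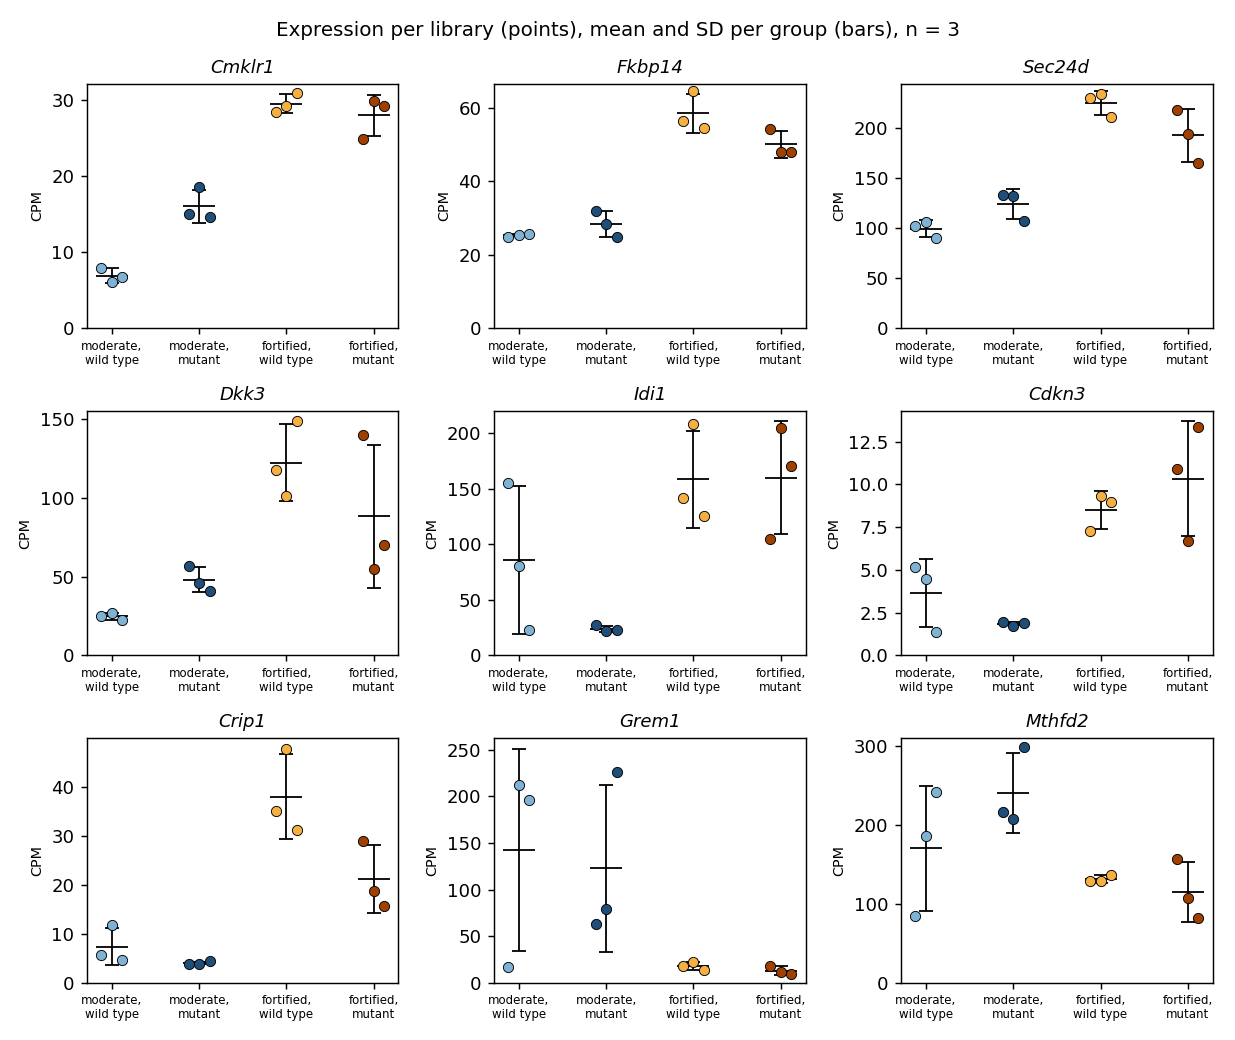
CPM (y axis, linear from 0) of 9 genes in the 4 groups (x axis). Points are single libraries and bars the mean and SD of 3; Cmklr1 lay at 29.5 CPM in fortified and 6.93 CPM in moderate wild type cells, and Idi1 at 159.7 and 24.0 CPM in fortified and moderate mutant cells.

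Camera called 5 of 36 lists in mutant cells, against 0 with an estimated correlation (adjusted p = 0.98 for each) and 0 by fry. Ribosomal protein genes were positive in 46 of 46 cases (median 0.76, adjusted p = 3.5e-12), and 9 rose over all genes against 24 adjusted over the list alone. Rpl11 rose 2.5-fold, from 428.2 ± 35.6 to 1072 ± 78.1 CPM, Rpl38 2.41-fold and Rpl5 2.24-fold. Mitosis genes were positive in 28 of 28 cases (median 1.19, adjusted p = 3.72e-11), with 6 passing over all genes and 25 adjusted over the list alone. Cdk1, the kinase that drives entry into mitosis, rose 3.37-fold, and the spindle protein Nusap1 3.65-fold. Cholesterol synthesis genes were positive in 22 of 22 cases (median 1.24, adjusted p = 9.9e-11), and 12 rose over all genes against 19 adjusted over the list alone. Fdps rose 3.20-fold, Pmvk 2.75-fold and Fdft1 2.49-fold. DNA replication genes were positive in 29 of 31 cases (median 0.76, adjusted p = 3.11e-06), 5 passing over all genes and 16 adjusted over the list alone, among them Gins1 (3.68-fold), Gins2 (2.66-fold), Prim1 (2.47-fold) and Tk1 (2.33-fold).

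Genes of the ATF4 and unfolded protein response were negative in 18 of 25 cases (median -1.15, adjusted p = 0.0347; adjusted p = 0.98 with an estimated correlation). Of these 6 fell and 1 rose over all genes, against 8 and 2 adjusted over the list alone. The cystine transporter Slc7a11 was 6.16-fold lower and the stress factor Atf3 4.37-fold lower, while Xbp1, the factor of the IRE1 branch, rose 2.03-fold. Sesn2, Vldlr and Slc3a2 fell by 1.32, 2.00 and 1.51 on the log2 scale. The 3 libraries apart on the first component had the lowest list scores: moderate wild type 1 (-0.904), fortified mutant 3 (-0.753) and fortified mutant 2 (-0.46). Fortified mutant 1 was at -0.0571, and the moderate mutant libraries at 0.354, 0.481 and 0.727. The list's call ended without moderate mutant 3 (adjusted p = 0.0557), fortified mutant 3 (0.0671, median -0.75), fortified wild type 2 (0.0509) or fortified wild type 3 (0.0543). The other 4 lists kept theirs without each of the 12 libraries. Shorter transcripts had higher log2 fold changes in this comparison (Spearman rho -0.31 across 14616 genes with a length). With each library's trend on transcript length removed, a setting chosen after the data were seen, 138 genes passed. The ribosomal median was then 0.37 (adjusted p = 1.17e-05), and those of mitosis, cholesterol synthesis and DNA replication were 1.20, 1.27 and 0.73.

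**Figure D3:**
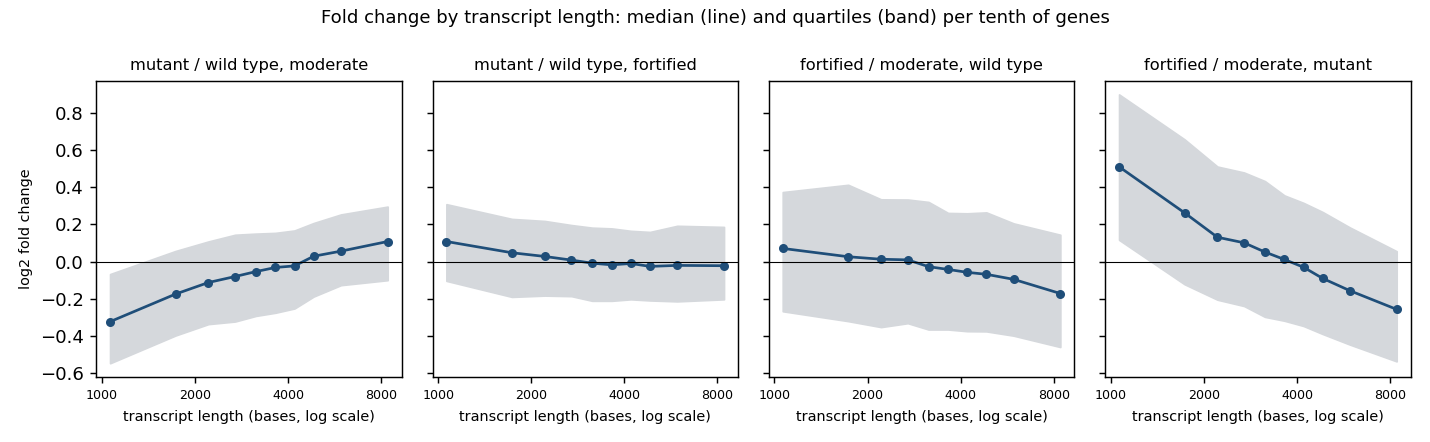
Log2 fold change (y axis) against transcript length in bases (x axis, log scale) for the 4 comparisons. Lines join the medians of 10 groups of genes of rising length and bands span the quartiles; in mutant cells the median ran from 0.51 in the shortest group to -0.26 in the longest.

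Among folate genes the share passing in mutant cells was near that of all genes (1053 of 15186). The list of 38 had a median of -0.147 (adjusted p = 0.693), with 2 genes higher and 1 lower over all genes, and 3 higher and 4 lower adjusted over the list alone. Tyms, the synthase that makes thymidylate, rose 2.75-fold (23.4 ± 0.895 to 64.4 ± 18.8 CPM, adjusted p = 0.0216), and Mat2b rose 1.64-fold (adjusted p = 0.0281). Mtrr, the reductase that reactivates methionine synthase, was 1.99-fold lower (adjusted p = 0.0363). Values that did not pass were -1.07 for Mthfd2 (adjusted p = 0.0742), -1.23 for Shmt2 (0.121) and -0.66 for the folate carrier Slc19a1 (0.208). Ciliary genes had a median of 0.0059 (adjusted p = 0.896) and 1 of 59 passed, Ift20, which rose 1.95-fold (adjusted p = 0.0372), against 0 adjusted over the list alone; the test's direction was negative although the median was positive. Hedgehog genes had a median of -0.0132 (adjusted p = 0.646) with 0 passing over all genes. Among neural tube closure genes (median -0.252, adjusted p = 0.284) the endocytic receptor Lrp2 fell by 2.57 on the log2 scale (adjusted p = 0.042). Tet3 and Kdm6b fell by 0.86 and 0.71 in a list of methylation enzymes that was not called (adjusted p = 0.066). The imprinted gene Plagl1 fell by 1.03 and Zrsr1 rose by 0.83, while Myc fell by 1.46. Of the hypoxia genes Ero1l and Vegfa fell by 1.84 and 1.48, and Ldha and Ankrd37 rose by 0.81 and 1.53.

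The fourth comparison asked how fortified differed from moderate folic acid in wild type cells. All 35 genes of the matrix list had positive log2 fold changes, with a median of 1.32. Over all genes 0 of them passed, and the list's adjusted p was 0.118 with an estimated correlation. Fkbp14, a prolyl isomerase of the endoplasmic reticulum that acts on collagens, rose 2.31-fold, from 25.4 ± 0.376 to 58.6 ± 5.36 CPM (adjusted p = 0.014). Sec24d, a coat protein of vesicles that carry procollagen, rose 2.27-fold, from 99.4 ± 8.45 to 225.2 ± 12.1 CPM (adjusted p = 0.0228).

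By edgeR 4 genes passed, all higher, and 2984 had an unadjusted p under 0.05. The others were Cmklr1, which rose 4.26-fold (6.93 ± 0.95 to 29.5 ± 1.26 CPM, adjusted p = 0.00086), and the secreted Dickkopf protein Dkk3, which rose 4.95-fold (24.7 ± 2.46 to 122.3 ± 24.4 CPM, adjusted p = 0.0328). Cmklr1 lies on chromosome 5 (113612354 to 113650426, minus strand), Fkbp14 on chromosome 6 (54577604 to 54597308, minus strand), Sec24d on chromosome 3 (123267455 to 123365641, plus strand) and Dkk3 on chromosome 7 (112116017 to 112159057, minus strand). All 3 fortified libraries lay above all 3 moderate ones for each of them. DESeq2 called 1197 genes (631 higher, 566 lower), limma-voom 17, and limma on log2(TPM + 1) 1. The groups did not overlap for 3134 genes (20.6%), where chance gives 10%.

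The wild type count turned on single libraries. It was 1012 without moderate wild type 1, 104 without moderate wild type 2 and 2 without moderate wild type 3. It was 1 without each of the fortified wild type libraries, 2 without moderate mutant 1, 1 without moderate mutant 2, and 260 without fortified mutant 1. Cmklr1 passed without each of the 12 libraries in turn. Fkbp14, Sec24d and Dkk3 passed in none of the fits without a fortified wild type library (lowest adjusted p 0.0582, for Fkbp14 without fortified wild type 3) or without moderate wild type 3 (lowest 0.0579, for Fkbp14) or moderate mutant 2 (lowest 0.0566, for Fkbp14). Sec24d and Dkk3 also lost their call without moderate mutant 1 (adjusted p = 0.0609 for each). Dkk3 lost its call without moderate mutant 3 (0.0585) or fortified mutant 3 (0.0533). Mutant libraries are not part of this contrast and enter it through the filter, the scaling and the spread shared by all groups. In the fits without a mutant library the log2 fold changes stayed at 2.31 for Dkk3, 1.18 for Sec24d and 1.21 for Fkbp14. Genes just short of the threshold (adjusted p = 0.0503) were Eln, with a log2 fold change of 2.32 (SE 0.35; 370.7 ± 166 to 1855 ± 151 CPM), and Cxadr (-2.01), Mfsd7c (-1.63), Pim1 (-0.84), Runx1t1 (-0.79) and Mbd1 (-0.76).

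Camera called 6 of 36 lists in wild type cells, against 0 with an estimated correlation and 1, the matrix list, by fry (adjusted p = 0.00264). It called 11 without moderate wild type 1, 10 without moderate wild type 2 and 11 without fortified wild type 3. The matrix list had an adjusted p of 7.01e-19 (adjusted p = 0.118 with an estimated correlation), and 24 of its 35 genes were higher when adjusted over the list alone, against 0 over all genes. Its smallest p values belonged to Eln, Mfap4 (2.18), Emilin1 (1.64) and Col3a1 (1.45), the last 3 with an adjusted p of 0.0539. The call held without each of the 12 libraries, with medians from 1.14 to 1.46. Cholesterol synthesis genes were positive in 22 of 22 cases (median 0.61, adjusted p = 1.72e-06), with 0 passing over all genes or adjusted over the list alone. Their median was 1.01 without moderate wild type 1 and 0.31 without moderate wild type 3. Canonical Wnt genes had a median of 0.40 (adjusted p = 0.0098), with 1 passing over all genes, Dkk3, and 4 adjusted over the list alone. The others of these were Lgr5 (3.58), Dkk2 (1.33) and Fzd2 (0.70). Mitosis genes had a median of 0.30 (adjusted p = 0.0071), myofibroblast genes one of 0.31 (adjusted p = 0.0098) and muscle markers one of -0.87 with 24 of 24 negative (adjusted p = 0.0098). With an estimated correlation the adjusted p was 0.945 for each of these 5 lists. Without moderate wild type 3 the mitosis median was -0.0286 (adjusted p = 0.771), and the Wnt and myofibroblast calls ended (adjusted p = 0.225 and 0.0964). Without fortified wild type 2 the mitosis, myofibroblast and muscle calls ended (0.0768, 0.235 and 0.422). Muscle markers had a median of -0.0433 (adjusted p = 0.521) without moderate wild type 1, the library with the highest muscle score, -0.46 without fortified wild type 2 and -1.48 without fortified wild type 3. The medians of mitosis and Wnt genes were 0.83 and 0.98 without moderate wild type 1. Those of Wnt and myofibroblast genes were 0.215 and 0.19 without moderate wild type 3, and without fortified wild type 2 that of myofibroblast genes was 0.17. Ciliary genes had a median of 0.059 (adjusted p = 0.80) and folate genes one of -0.22 (adjusted p = 0.414), with 0 passing in either list.

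**Figure D4:**
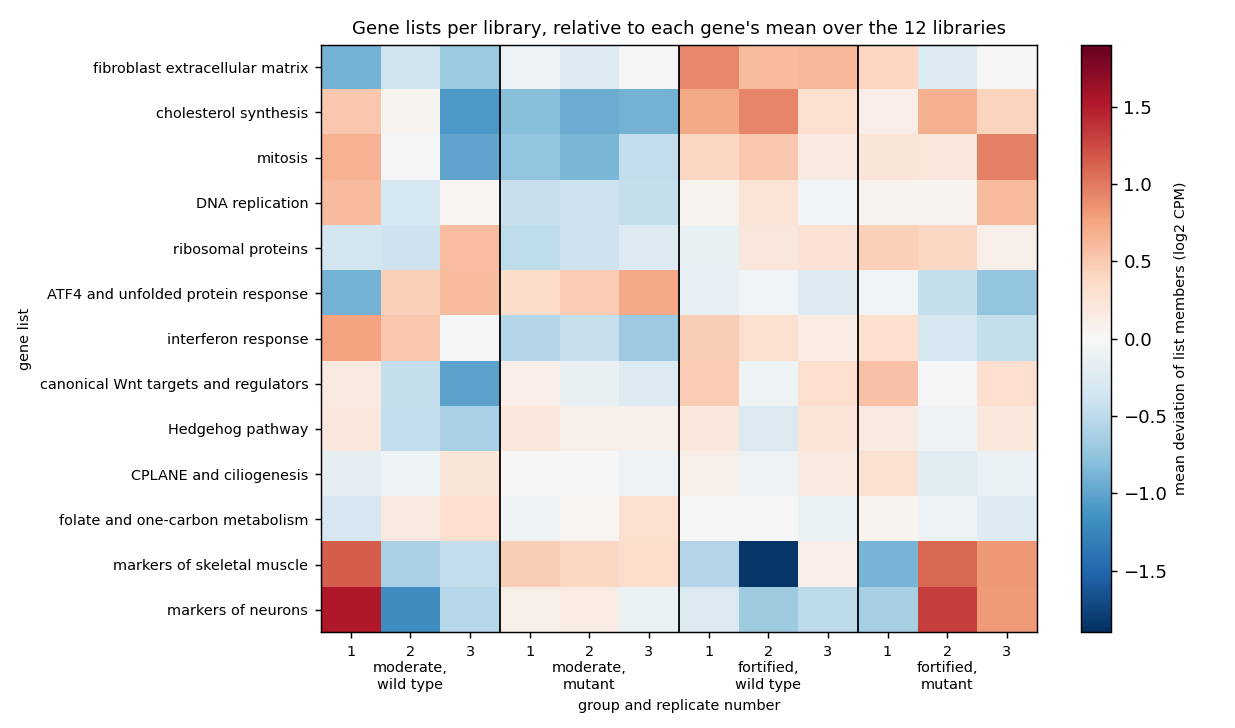
Mean deviation of the genes of 13 lists (y axis) in each of the 12 libraries (x axis), in log2 CPM relative to each gene's mean over all libraries (colour scale). Matrix genes lay at 0.911, 0.601 and 0.627 in the fortified wild type libraries and at -0.892, -0.379 and -0.699 in the moderate wild type libraries.

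For several lists no comparison passed. Their medians follow in the order mutant against wild type at moderate and at fortified folic acid, then fortified against moderate in wild type and in mutant cells. They were 0.133, 0.123, 0.218 and 0.253 for limb and craniofacial patterning genes and 0.315, 0.0343, -0.0627 and -0.188 for Hox genes of the hindbrain and neck. For imprinted genes they were 0.0559, 0.196, -0.0488 and 0.0763, and for p53 targets 0.0263, 0.126, -0.369 and -0.312. Markers of fat gave -0.588, -0.739, -0.654 and -0.493, those of endothelium 0.15, 0.077, -0.181 and -0.142, and those of epithelium -0.284, 0.379, -0.601 and 0.12. Markers of kidney and gonad mesoderm gave -0.139, -0.108, -0.271 and -0.31, and those of liver -0.801, -0.47, 0.101 and 0.282. The lowest adjusted p among these was 0.0606, for the hindbrain and neck Hox genes at moderate folic acid. Neural tube closure genes had a median of -0.20 (adjusted p = 0.143) for folic acid in wild type cells.

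Responses to folic acid in wild type and mutant cells shared their direction more often than not. Their log2 fold changes had a Pearson r of 0.496 and a Spearman rho of 0.488 across 15186 genes, which are not independent replicates, and the sign was the same for 68.6%. Leaving out single libraries gave a Pearson r from 0.268 (without fortified mutant 1) to 0.62 (without moderate wild type 1). Of the 1053 genes called in mutant cells, 1010 (95.9%) had the same sign in wild type cells, where the higher ones had a median of 0.36 and the lower ones of -0.54, against 0.98 and -0.87 in mutant cells. Cmklr1, Fkbp14 and Sec24d passed in both, where 0.168 shared genes would be found if the calls were independent (one-sided Fisher's exact test, p = 0.000285). That test treats genes as independent, and both contrasts use the same fitted spread per gene. Its p therefore does not measure variation between libraries. DESeq2 gave 529 shared genes, and without moderate wild type 1, moderate wild type 2 and fortified mutant 1 there were 569, 26 and 22. There were 0 without moderate mutant 1, 2 or 3 or fortified mutant 2, and 1 without each of fortified wild type 1, 2 and 3.

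That 1053 genes passed in mutant and 4 in wild type cells was not matched by a passing interaction for any gene by edgeR. The test of the interaction of genotype and folic acid called 0 genes by edgeR, with 1015 at an unadjusted p under 0.05 and a lowest adjusted p of 0.708; DESeq2 called 8 (1 higher, 7 lower) and limma-voom 0. The smallest p values, none passing, were for Gins2 (1.32), Cox7a2 (1.36), Sec61g (1.19), Tbca (1.06) and Ndufb5 (1.00) among genes with a higher response in mutant cells. Cmklr1 (-1.29), Col11a1 (-1.60), Pcdhga5 (-1.66), Itga11 (-2.70) and Eln (-2.08) had the smallest among those with a lower one. Eln stood at 370.7 CPM in moderate wild type, 1088 in moderate mutant, 1855 in fortified wild type and 1292 in fortified mutant cells.

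Averaged over genotype, 1351 genes were higher and 1345 lower in fortified than in moderate cells by edgeR, 2696 in all and 685 of them by more than 2-fold. DESeq2 called 3942. Without moderate mutant 1, 2 and 3 the count was 1788, 1441 and 1411, and without fortified wild type 3 it was 1411. The largest averaged rises were those of the matrix proteins Thbs4 (2.96) and Tnn (2.62), the glycosyltransferase A4galt (2.85), Clec11a (2.49) and Crip1 (2.38). Without fortified mutant 1 A4galt was at 1.54 and Clec11a at 1.6, both still passing, and Tnn at 1.97. A4galt did not pass without moderate mutant 2 or 3, moderate wild type 3 or fortified wild type 3 (adjusted p = 0.0581, 0.0598, 0.0513 and 0.0576). Among the largest falls were those of the carbonic anhydrase Car6 (-5.37), Ppp1r16b (-4.26), Gch1 (-3.69) and Cdsn (-3.32), each with an adjusted p of 0.0226 or less. Cdsn did not pass without fortified wild type 3 (adjusted p = 0.055), and was at -3.94 without fortified mutant 1. Car6 was at -6.78 without fortified mutant 1 and -4.77 without moderate wild type 3. Hhip, an inhibitor of Hedgehog signalling, fell by 1.22 on the log2 scale (adjusted p = 0.0268) and methionine synthase (Mtr) by 0.44 (adjusted p = 0.0495). Of the lists, 19 of 35 matrix genes, 17 of 22 cholesterol genes, 11 of 28 mitosis genes, 10 of 46 ribosomal genes and 5 of 31 replication genes rose, and 4 of 30 methylation enzymes fell. Adjusted over the list alone these counts were 21, 20, 22, 14, 7 and 4. All 6 lists passed camera (adjusted p from 1.34e-09 to 0.0453), none with an estimated correlation (adjusted p = 0.977), and the matrix list by fry (adjusted p = 0.0211). Keeping only the 8 libraries with Xist leaves 1 wild type library per diet. The wild type part of the average then sets 1 library against 1, so that setting cannot decide on averaged folic acid. On log2(TPM + 1) 15.69% of 3741 called genes were higher, with a median of all genes of -0.15, and with library totals alone 34.26% of 2884 were higher.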

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

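The removal of length and GC trends, the settings with fewer libraries, the use of the sex-linked covariate to test for sex, and the respiratory chain list were tests chosen only after the result was seen; the covariate itself was among the alternatives set before.

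For 14 gene lists, the genotype effect differed between moderate and fortified folic acid by the interaction test of camera with its preset correlation. With an estimated correlation none passed, the adjusted p of these lists running from 0.122 to 0.937. By edgeR 0 single genes passed the interaction, with 1015 at an unadjusted p under 0.05 and 8 called by DESeq2. The matrix list had an adjusted p of 1.13e-18 and an interaction median of -1.07, from a genotype median of 0.45 at moderate and -0.59 at fortified folic acid. Ribosomal proteins (median 0.63) had an adjusted p of 8.26e-10, DNA replication (0.76) 2.01e-09 and mitosis (0.93) 2.62e-06. Myofibroblast genes (-0.33) and neuron markers (1.51) both had 0.00519, and Hedgehog (-0.31) and cholesterol synthesis genes (0.65) both 0.00653. Planar cell polarity genes (-0.26) had 0.00685, bone markers (-0.89) 0.00933, muscle markers (1.02) 0.016, ATF4 genes (-0.27) 0.0191, interferon genes (0.53) 0.0264 and TGF-beta and YAP genes (-0.24) 0.0315. Without the 3 libraries apart on the first component, which had the highest muscle and neuron scores, the interaction medians of muscle and neuron markers turned to -1.18 (adjusted p = 0.000496) and -1.22 (3.32e-06). In that setting the lone fortified mutant library is assumed to vary like the other groups. The medians of bone markers (-0.50, adjusted p = 0.758), mitosis (0.0522, 0.758), cholesterol synthesis (-0.0447, 0.343) and ATF4 genes (-0.13, 0.649) no longer passed. The other 8 lists did, though DNA replication moved to 0.21, myofibroblast genes to -1.22, TGF-beta and YAP genes to -0.82, planar cell polarity genes to -0.56 and Hedgehog genes to -0.64. Another 10 lists, not called with all libraries, passed in this setting.

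With a real value of 0, counting regroupings with as many single genes decides nothing: for the interaction it was 100 of 100 by necessity. There 1 regrouping called 138 genes and each of the others 1 at most.

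The first pattern weighed was the 1053 genes called between fortified and moderate folic acid in mutant cells. A GC-dependent difference is argued against as the whole cause, since 84.8% of the genes with a GC value stayed called in the same direction once it was removed. A length-dependent difference stays open: with it removed 13.5% stayed called, and all 1007 genes with a length kept their sign. Their median change went from 0.941 (SD 0.558) to 0.779 (SD 0.591), with a median SE of 0.204 and 0.203. Of these genes 927 still had an unadjusted p under 0.05. The largest unadjusted p that passed was 0.000468, against 0.00346 before. Why the calls ended was not tested. The 2 fortified mutant libraries with high muscle and neuron markers cannot be told apart from folic acid as the cause by the sign in fortified mutant 1, where 100% of the genes had the same sign; this met the bound set beforehand, but the bound was wrong, because the genes were selected with this library in the group and each of the 3 libraries gives 100. Without the 3 libraries apart 1104 genes passed and 504 of the 1053 (47.9%) stayed called, on 1 fortified mutant library assumed to vary like the other groups, which leaves this open. The labels give no day or batch of culture and no embryo or litter, so folic acid, handling and litter stay open.

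The second pattern was that no single gene passed between mutant and wild type cells by edgeR. DESeq2 called 50 genes at moderate and 6 at fortified folic acid, and 18 for the average, so the pattern depends on the method. An effect too small or too variable for 3 libraries per group is consistent with the simulated data, in which 19.2% of 2-fold changes were called at moderate folic acid. A difference in sex between the wild type libraries stays open: with the sex-linked score as covariate edgeR called 0 genes for genotype averaged over folic acid, which decides nothing where 53.2% of simulated 2-fold changes were recovered even without the covariate. For the same average, 100 of 100 regroupings gave as many genes as the real value of 0, again by necessity; 3 of them called from 138 to 225 (highest other 225) and the rest 4 at most, so a structure of the samples beyond genotype may be present. That the mutation changes few transcripts in these cells stays open as well.

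For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. For genes between mutant and wild type cells the real value was 0, so all 10 splits gave as many by necessity at moderate (highest other 0) and 10 at fortified folic acid (highest other 3). For folic acid it was 2 splits in wild type cells (4, highest other 4) and 1 split, the real one, in mutant cells (1053, highest other 0). Over all 12 libraries, 1 of 100 regroupings, the real one, gave as many genes for folic acid averaged over genotype (2696, highest other 1619). Of the 99 others 3 called from 581 to 1619 genes and the rest 1 at most. A share of 1 in 100, under 0.05, argues against a random split there but does not exclude it. For lists it was 1 split for genotype at moderate folic acid (19, highest other 18) and 10 at fortified folic acid (8, highest other 18). It was 10 splits for folic acid in wild type cells (6, highest other 24) and 10 in mutant cells (5, highest other 19).

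The third pattern was found by looking at the called genes, and is a hypothesis. Genes of respiratory chain and ATP synthase subunits were higher in fortified than in moderate mutant cells, with a median log2 fold change of 0.811 and 74 of 77 positive. Their short transcripts (median 1141 bases, against 3393 for all genes) stay open as the cause. The median lay above the central 95% of 10000 random lists matched for length and expression (0.298 to 0.573), which met the bound set beforehand, but that bound was wrong, because the list was chosen after its genes were seen among the called ones (45 of 77). The median was 0.403 with the length trend removed, 0.477 on log2(TPM + 1) and 0.171 in wild type cells, and no biological explanation was tested.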

How the results depend on the processing

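The removal of length and GC trends, leaving out 3 libraries and keeping only libraries with Xist were tests chosen only after the data were seen. Gene counts for genotype and the interaction were 0 by edgeR and in each setting run except DESeq2. Comparisons are given as genotype at moderate and fortified folic acid, then folic acid in wild type and mutant cells. Where no reason is given for a change, the cause was not tested.

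DESeq2 called 50, 6, 1197 and 2414 genes, 8 for the interaction and 18 for averaged genotype. Its genotype correlation was 0.411, with 3 shared genotype and 529 shared folic acid calls. Camera with an estimated correlation called 0, 0, 0 and 0 lists, and fry 0, 0, 1 and 0.

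For folic acid in wild type cells, 2 genes passed with library totals only, 80 without a low-count filter, 39 with 1 CPM in 3 libraries, 2 with only the groups compared and 17 by limma-voom. It was 1 on log2(TPM + 1), 13 on log2(TPM + 0.1) and 13 with the sex-linked covariate. In mutant cells 2091 passed with only the groups compared, 5273 by limma-voom, 2814 on log2(TPM + 1) and 2805 on log2(TPM + 0.1). Against a 1.5-fold change it was 1 in wild type and 0 in mutant cells, and 17 for averaged folic acid, a stricter question by construction. Without a filter the folic acid correlation was 0.247 and 29 calls were shared. With the sex-linked covariate 11 lists were called for genotype at moderate folic acid and 10 for folic acid in wild type cells, and the genotype correlation was 0.638, where the genotype effects share the error of the fitted covariate.

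No label says that the replicate numbers pair the libraries. Of 18 same-number pairs 4 had a residual r over 0.1 (median -0.0033, against 0.02 for other pairs). These values do not exclude a shared litter or day. With the replicate numbers as a block, 65 and 559 genes passed for folic acid in wild type and mutant cells, and 28 were shared.

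With the length trend removed these counts were 33 and 138, with the GC trend removed 25 in wild type cells, and with both removed 87 and 175. Without the 3 libraries apart 1298 genes passed in wild type cells, and 11 and 18 lists in wild type and mutant cells. Among libraries with Xist 0 and 2045 genes passed, 0 for averaged folic acid, and 11 lists for genotype at moderate folic acid and 14 for folic acid in wild type cells. In these settings a lone library in a group is assumed to vary like the other groups.

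Leaving out each library in turn gave 0 to 0 genes for genotype at moderate and at fortified folic acid, for averaged genotype and for the interaction. For folic acid it gave 1 to 1012 genes in wild type cells, 0 (without moderate mutant 1 or 2) to 2073 in mutant cells and 1411 (without moderate mutant 3 or fortified wild type 3) to 4025 averaged. The highest of each came without moderate wild type 1. Shared calls ran from 0 to 569 for folic acid and 0 to 0 for genotype. The folic acid correlation ran from 0.268 to 0.62, and the genotype correlation from -0.137 (reversed, without moderate wild type 2) to 0.459. Lists called ran from 11 to 23, 8 to 14, 5 to 11 and 4 to 6.

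Over the named genes followed through the settings, 443 values kept direction and side of the threshold, 114 lost their call, 8 gained one, 3 moved and 0 reversed. These values include genes not called with all libraries, such as Rsg1. Of the fits without 1 library they hold only the lowest and highest fold change per gene, so lost calls are undercounted. Without moderate mutant 1, 2 or 3, 0 of 20 named genes passed in mutant cells. Depth limits little beyond genes near the filter, such as Rsg1 with 19 to 54 counts.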

Other observations

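The test on X-linked genes below was set out before its value was seen, and the choice of library was made after the sex-linked transcripts were seen.

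Fortified wild type 2 carried neither Xist nor Y-linked transcripts. A candidate explanation is cells with 1 X chromosome and no Y chromosome: Kdm6a, Ddx3x, Eif2s3x and Kdm5c summed to 1115 CPM there, against 1176 to 1884 in 8 libraries with Xist, though the 3 libraries with Y-linked transcripts (896 to 1790) overlapped both.

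Trends of library values on transcript length, as Spearman rho, were 0.34, 0.26 and 0.25 in the moderate mutant libraries and 0.15, 0.02 and -0.12 in the moderate wild type libraries. They were -0.28, -0.2 and 0.034 in the fortified mutant libraries and 0.075, -0.2 and -0.23 in the fortified wild type libraries. Across genes, rho of log2 fold change on length was 0.28 and -0.082 for genotype at moderate and fortified folic acid, and -0.11 and -0.31 for folic acid in wild type and mutant cells.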
